A study of Rattus norvegicus with 9 samples.

How the data were processed

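RNA from rat adrenal zona glomerulosa cells was measured on 9 Affymetrix Rat Genome 230 2.0 arrays, 1 per tube of cells. Per the labels, cells were dispersed enzymatically and mechanically, incubated for 2 h, and total RNA was column-purified, treated with deoxyribonuclease and biotin-labelled by the manufacturer's standard procedure. The deposited values are 1 linear intensity per probe set and array. The submitters' processing notes name GCOS, the array maker's operating software, without a version. The background method and probe set summary are not given in the sources used here. In the deposited intensity values the mean without the lowest and highest 2% was between 500.17 and 500.19 on each array, so a common scaling had been applied, while array medians lay between 128.5 and 173.1. Detection calls were not used here.

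The table held 31099 probe sets, of which 57 were control probe sets and were left out of the tests. Genes were named through the platform annotation, with symbols updated from a table of RefSeq genes of assembly GRCr8, which was used for names only, and no coordinates are given. A single symbol was found for 20826 probe sets (20758 through the Entrez identifier, 2 through an accession and 66 by the annotation's own symbol), covering 14217 genes. Several symbols were listed for 436 probe sets and none for 9780, and these were counted but never named.

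Values were transformed as log2(signal + 16). Probe sets were tested if their mean over the 9 arrays lay above the 40th percentile, which left 18625. The design called for further scaling if array medians differed by over 10%, without saying over which probe sets. The rule was read over the tested probe sets, where the medians differed by 8.58% (392.5 to 426.2), and no scaling was applied. Over all 31042 probe sets that were not controls they differed by 35.0% (128.0 to 172.9), so the rule read that way would have called for scaling. Scaling to that median was added as an alternative after the data had been seen. Groups and replicate numbers came from the sample titles. All 9 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with the 3 groups and the cell preparation as a fixed block, which left 4 residual degrees of freedom beside 10.7 of the variance prior. The contrasts were Ang II against control, potassium against control and Ang II against potassium. Benjamini-Hochberg adjustment was made over the 18625 probe sets of each contrast, with a threshold of 0.05.

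The pairing of arrays comes from the design text, in which each of 3 independent preparations supplied 1 tube per group. It was checked on the deviations from the group means. The 9 pairs of arrays of 1 preparation correlated at 0.09 to 0.27, and arrays of different preparations at -0.21 to 0.05. In all 18 of 18 comparisons an array correlated best with the array of its own preparation in another group.

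Named genes were chosen by a rule. For each stimulus against control it took the 12 largest increases and the 8 largest decreases, and for Ang II against potassium the 8 largest in each direction. Only probe sets past the threshold, with 1 gene symbol and the same direction in all 3 preparations, were eligible, and a gene was represented by its probe set with the smallest p. The rule added Star, Cyp11a1, Hsd3b1, Cyp21a1, Cyp11b1, Cyp11b2, Nr4a1, Nr4a2, Nr4a3, Fos, Egr1, Agtr1a, Agtr1b and Mc2r, whatever their result, and up to 4 members of each gene list with the smallest p in each comparison. Cyp11b2 and Mc2r were not analysed here, since no tested probe set was named for either alone.

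There were 24 gene lists with 598 entries, of which 546 matched a named probe set, 1 probe set per gene (that with the highest mean). They covered steroid hormone synthesis, cholesterol synthesis and uptake, immediate early transcription factors, CREB and calcium target genes, feedback regulators of MAP kinase and G protein signalling, angiotensin receptors, calcium and kinase signalling, potassium, calcium and sodium transport, cytokines, chemokines and adhesion, growth factors and matrix signals, heat shock and protein folding, amino acid and oxidative stress response, circadian clock, cell cycle and oxidative phosphorylation. The other 10 held markers of zona glomerulosa, zona fasciculata, medulla, endothelium, macrophage, capsule fibroblast, smooth muscle and pericyte, T and B lymphocyte, red blood cell and adipocyte. Shifts of lists were tested with limma's camera (preset correlation 0.01) and adjusted over the 72 tests of 24 lists and 3 contrasts, 15 of which passed. Camera with an estimated correlation and camera on the mean of all tested probe sets of a gene were alternatives. Fry was run beside them and tests a list against no change, a different question. Of the 15, 1 held with an estimated correlation, that of the immediate early transcription factors after Ang II. That version tests on the 4 residual degrees of freedom and so has less power, whatever the correlation.

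For the shared controls, 100 draws without any effect were simulated, once with independent genes and once with whole-array deviations. Every array was simulated, the controls included, so the observed control values were not kept. The fits were tested on simulated data with 200 changed probe sets among 18625. For Ang II against control, 48.5% of the 68 probe sets changed by 0.5 on the log2 scale were recovered, 74.2% of the 66 changed by 1 and 100% of the 66 changed by 2, with 7 false calls. For potassium against control the shares were 45.6%, 80.3% and 97.0%, with 12 false calls. A list of 43 genes raised by 0.3 was called by camera, and 0 of the 23 other lists were. The simulated noise was normal and independent between probe sets, with the fitted variances. These figures therefore do not cover correlated genes or a deviating array. In the data the raised list, oxidative phosphorylation, had an estimated correlation of 0.18.

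Alternatives were the fit without the preparation or with it as a random block, only the arrays of the groups compared, quantile normalization, centring on the median of the tested probe sets, pseudocounts of 1 and 64, no filter or a filter at the 60th percentile, no intensity trend, a robust variance prior, array weights, and leaving out each array and each preparation. Array quality was described by the 3′ to 5′ ratios of Gapdh and beta-actin and by the spiked control probe sets. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.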

Results

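Transcript levels were measured in freshly isolated rat adrenal zona glomerulosa cells, the outer layer of the adrenal cortex, which makes aldosterone. The cells were left untreated, or were exposed for 2 h at 37 °C to angiotensin II (Ang II, 100 nM) or to raised potassium (16 mM), the peptide and the ion that stimulate aldosterone secretion. Each of 3 independent cell preparations was divided into 1 control, 1 Ang II and 1 potassium tube, so that each group held 3 arrays and the series 9. Each array, an Affymetrix Rat Genome 230 2.0 chip, gave 1 linear signal per probe set. The trimmed mean signal was 500 on every array. Of 31042 probe sets that were not controls, the 18625 with the higher mean signals were tested. Fold changes are on the log2(signal + 16) scale, which understates the change of dim probe sets, and the number of arrays limits their precision. The model, the gene lists, the rule for the genes named and most alternative settings were chosen before the data were examined. The rule for scaling the arrays had not named the probe sets to judge it on, and its reading decided that none was scaled. Errors are standard errors (SE) of the fitted log2 fold change or standard deviations (SD) of the 3 signals of a group, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

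The comparison of Ang II with control asks which transcripts the hormone changed within 2 h. Ang II raised genes of several kinds, and the rule for naming them required the same direction in all 3 preparations. Serpinb2, which encodes plasminogen activator inhibitor 2, rose 6.55-fold, from a signal of 164 ± 30.0 to 1154 ± 111 (SD, n = 3). Giot1, which encodes a zinc-finger repressor of transcription, rose 4.04-fold, from 1864 ± 343 to 7530.4 ± 938. Srxn1, whose product sulfiredoxin repairs oxidised peroxiredoxins, rose 3.73-fold, from 532 ± 157 to 1989 ± 281. The probe set of Fancc with the smallest p, a gene of the Fanconi anaemia DNA repair complex, had the largest increase among the named genes, 3.02 ± 0.25 on the log2 scale (SE). Of the other 2 tested probe sets of Fancc, both were higher and 1 passed the test.

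In total 409 of the 18625 probe sets passed an adjusted p of 0.05 after Ang II, 310 of them higher and 99 lower, and all 409 moved the same way in the 3 preparations. In this and the other comparisons, a call made with the preparation as a block nearly entails such agreement, so it is no separate evidence. A change of over 2-fold was seen for 38 of the higher and 13 of the lower probe sets. The other genes with the largest increases were Sprr1a, a small proline-rich protein (log2 fold change 2.44 ± 0.20, SE), the neuropeptide gene Nmu (2.34 ± 0.44), Ypel4 (2.09 ± 0.24), the vesicular glutamate transporter Slc17a6 (1.99 ± 0.27), Vom2r53 (1.79 ± 0.29), the kinase gene Dclk1 (1.66 ± 0.14), Klhl41 (1.45 ± 0.26) and the matrix metalloproteinase gene Mmp3 (1.41 ± 0.15). Their adjusted p-values lay between 6.9e-06 for Sprr1a and 0.0087 for Nmu. Among the largest decreases only Osgin1 had a high signal. It fell 2.15-fold, from 5231 ± 441 to 2442 ± 366, with an adjusted p of 6.9e-06. The other large decreases, with log2 fold changes from -1.14 to -1.66, were of Necab2, Art1, Rpusd3, Prkag2, Slc2a6, Micall2 and Hoxd4, whose control signals lay between 153 ± 13.5 for Rpusd3 and 383 ± 80.8 for Micall2. The calls of Rpusd3, Necab2, Slc2a6, Prkag2, Hoxd4, Art1 and Nmu ended in 16, 14, 14, 11, 11, 7 and 7 of the alternative settings.

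Of 35 measured immediate early transcription factors, the genes that cells switch on first after a stimulus, 15 rose after Ang II, 1 fell and 19 did not pass the test. Adjusted over the list alone, 26 rose and 1 fell. The median log2 fold change of the list was 0.34, and the list was shifted upward by camera (adjusted p = 4.8e-15). The shift was still called with an estimated correlation (adjusted p = 0.048). Egr4 rose by 1.29 ± 0.10 on the log2 scale, Csrnp1 by 0.82 ± 0.06 and Egr1 by 0.41 ± 0.06. The 3 orphan nuclear receptors of the Nr4a family all rose, Nr4a1 by 0.80 ± 0.11, the brighter probe set of Nr4a2 by 0.79 ± 0.14 and Nr4a3 by 0.58 ± 0.09. Klf10, a TGF-beta-inducible zinc-finger factor, fell (-0.89 ± 0.10, adjusted p = 9.9e-05). Fos had a log2 fold change of 0.20 ± 0.07 and did not pass the test (adjusted p = 0.17).

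CREB and calcium target genes rose in 14 of 26 cases and fell in none, with a median log2 fold change of 0.39 (camera adjusted p = 4.6e-10, and adjusted p = 0.23 with an estimated correlation). Adjusted over the list alone, 17 rose. Examples were the salt-inducible kinase gene Sik1 (0.97 ± 0.14), the cyclooxygenase gene Ptgs2 (0.84 ± 0.10) and the transcription factor Nfil3 (0.68 ± 0.09). Among feedback regulators of MAP kinase and G protein signalling, 9 of 32 rose and none fell, over all probe sets and adjusted over the list alone (median 0.15, camera adjusted p = 8.1e-07, adjusted p = 0.23 with an estimated correlation). Spry2, an inhibitor of receptor tyrosine kinase signalling, rose by 0.85 ± 0.07, the EGF receptor inhibitor gene Errfi1 by 0.71 ± 0.08 and the cytokine signalling inhibitor gene Cish by 0.86 ± 0.09. Of 25 heat shock and protein folding genes 5 rose and none fell, and 9 rose adjusted over the list alone (median 0.11, camera adjusted p = 2.5e-04, adjusted p = 0.30 with an estimated correlation). The members that rose were small heat shock proteins and co-chaperones, such as Cryab (0.54 ± 0.07) and Dnajb4 (0.43 ± 0.06).

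Few genes of steroid hormone synthesis passed the test. Of 19 measured, 3 rose after Ang II, none fell, and the list as a whole was not shifted (camera adjusted p = 0.68). Adjusted over the list alone, 3 rose and 1 fell. Star, whose product carries cholesterol to the inner mitochondrial membrane, rose 1.23-fold, from 18873 ± 2050.5 to 23042 ± 734 (SD, n = 3), with an adjusted p of 0.024. Scarb1, the receptor that takes up cholesterol from high-density lipoprotein, rose by 0.46 ± 0.07 on the log2 scale, and Mrap, the accessory protein of the ACTH receptor, by 0.34 ± 0.08. The call of Star ended in 12 of the alternative settings and that of Mrap in 13. Cyp11a1, the side-chain cleavage enzyme, had a log2 fold change of -0.01 ± 0.06, Hsd3b1 0.00 ± 0.06, Cyp21a1 -0.09 ± 0.06 and Cyp11b1 0.08 ± 0.11, none of which passed the test. In the controls the mean signals of Cyp11a1, Hsd3b1, Cyp21a1 and Star were 24712, 25199, 20780 and 18873, in the upper range of the arrays, whose highest signals lay between 33568 and 42803, and whether saturation compressed their fold changes was not tested. Cyp11b2 and Mc2r were not analysed here. The angiotensin receptor genes Agtr1a (0.02 ± 0.10) and Agtr1b (-0.05 ± 0.08) did not pass the test either, nor did any of the 31 measured genes of angiotensin receptors, calcium and kinase signalling in limma's test, also adjusted over the list alone. At an unadjusted p of 0.05, 1 was higher and 3 were lower (camera adjusted p = 0.99).

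In the list of cholesterol synthesis and uptake, 2 of 25 genes rose after Ang II, both enzymes of the pathway, Idi1 by 0.68 ± 0.07 and Msmo1 by 0.55 ± 0.08 (camera adjusted p of the list 0.065, and 0.047 with quantile normalization). The counts were the same adjusted over the list alone. Of 33 genes of growth factors and matrix signals 7 rose and 1 fell, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.065, median log2 fold change -0.01 with an upward camera direction, and adjusted p = 0.043 with the mean of all tested probe sets of a gene). The urokinase gene Plau rose by 0.45 ± 0.09, its receptor gene Plaur by 0.58 ± 0.09 and Bmp2 by 0.51 ± 0.07. Of 26 genes of the amino acid and oxidative stress response 3 rose, Srxn1, Cdkn1a and Gadd45a, and none fell, while 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.089). The calls of Plau, Cdkn1a and Gadd45a ended in 10, 9 and 8 of the alternative settings. Cytokines, chemokines and adhesion genes showed 1 increase and 2 decreases among 26 (2 and 2 adjusted over the list alone, camera adjusted p = 0.38).

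**Figure D1:**
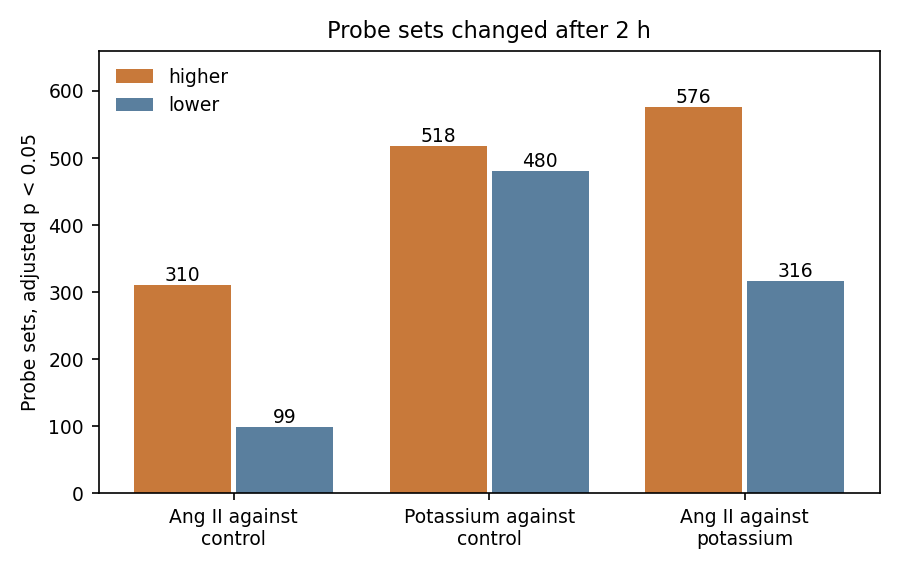
Number of probe sets with an adjusted p under 0.05 in each of the 3 comparisons, higher and lower shown as separate bars. Ang II changed 310 upward and 99 downward, potassium 518 and 480.

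Without the replicate block, that is with the preparation left out of the model, 197 probe sets passed the test after Ang II, without a trend of variance with intensity 38 did, and scaling each array to the common median of all probe sets gave 431 higher and 33 lower, with the median log2 fold change of all probe sets moved from -0.03 to 0.09. The count was 211, 221 and 233 without Ang II replicates 1, 2 and 3, 277, 244 and 274 without control replicates 1, 2 and 3, and 143, 254 and 244 without preparations 1, 2 and 3.

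The comparison of potassium with control asks the same of the ion. Potassium raised Ypel4, a gene of the yippee zinc-finger family, 17.5-fold, from a signal of 59.6 ± 29.1 to 1234 ± 132 (SD, n = 3), the largest increase among the named genes. Nr4a2 rose 5.13-fold at its probe set with the smallest p, from 502 ± 124 to 2598 ± 208. Giot1 rose 4.34-fold to 8081 ± 796, and the homeobox gene Hhex rose 3.91-fold, from 2089 ± 583 to 8027 ± 896. Osgin1 fell 3.15-fold, to 1661 ± 298, and the membrane protein gene Sema4b fell 3.04-fold, from 2503 ± 296 to 814 ± 97.8.

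Potassium changed 998 probe sets, 518 higher and 480 lower, and all 998 moved the same way in the 3 preparations. Of these, 86 rose and 50 fell by over 2-fold. The other genes with the largest increases were Nmu (log2 fold change 2.85 ± 0.44, SE), the kinase gene Dyrk3 (2.57 ± 0.17), Iqub (2.06 ± 0.21), the helix-loop-helix factor Scx (1.95 ± 0.12), Tent5a (1.95 ± 0.10), Spata2L (1.93 ± 0.29), the zinc-finger factor Osr2 (1.92 ± 0.09) and the somatostatin receptor gene Sstr1 (1.92 ± 0.34). Their adjusted p-values ran from 7.6e-09 for Osr2 to 0.003 for Sstr1. The other large decreases were of the small GTPase gene Rab7b (-1.69 ± 0.17), Mapk7 (-1.67 ± 0.37), the monocarboxylate transporter Slc16a9 (-1.58 ± 0.25), the glutamate receptor gene Grm8 (-1.57 ± 0.42), the troponin gene Tnni1 (-1.54 ± 0.36) and Hmx1 (-1.46 ± 0.33). Grm8 rested on variable control signals, 426 ± 444 (SD, n = 3), and its call ended in 13 of the alternative settings, while those of Tnni1, Hmx1 and Mapk7 ended in 8, 7 and 7.

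CREB and calcium target genes formed the list with the largest shift after potassium. Of 26 measured, 15 rose, none fell and 11 did not pass the test, and 17 rose adjusted over the list alone. The median log2 fold change was 0.60 (camera adjusted p = 7.4e-16, and adjusted p = 0.23 with an estimated correlation). Rgs2, a regulator of G protein signalling, rose 3.16-fold, from 4354 ± 541 to 13725 ± 695. The neurotrophin gene Bdnf rose by 1.66 ± 0.13 on the log2 scale, the brighter probe set of Nr4a2 by 1.94 ± 0.14 and Nr4a3 by 1.14 ± 0.09. Nr4a1 rose by 0.82 ± 0.11. The 1 other tested probe set of Bdnf had the opposite sign in all 3 comparisons and did not pass the test. Feedback regulators of MAP kinase and G protein signalling rose in 5 and fell in 2 of 32 cases, or 9 and 2 adjusted over the list alone (median 0.10, camera adjusted p = 0.0024, adjusted p = 0.30 with an estimated correlation). The phosphatase gene Dusp14 rose by 0.77 ± 0.09 and the cytokine signalling inhibitor gene Socs5 fell (-0.80 ± 0.07).

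Immediate early transcription factors went both ways after potassium, with 9 of 35 higher and 5 lower, or 12 and 9 adjusted over the list alone, and the list was not called as shifted (camera adjusted p = 0.066, but 0.015 without the replicate block and 0.037 with the mean of all tested probe sets of a gene). Junb rose by 1.11 ± 0.08 and Klf4 by 1.00 ± 0.08. Egr1 fell (-0.24 ± 0.06, adjusted p = 0.029), a call that ended in 15 of the alternative settings, among them median centring and scaling to the median of all probe sets. Fos had a log2 fold change of 0.21 ± 0.07 and did not pass the test.

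Cytokines, chemokines and adhesion genes were shifted downward by potassium. Of 26 measured, 6 fell and none rose, and 8 fell adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 0.0042, adjusted p = 0.47 with an estimated correlation, and 0.051 without the replicate block). The transcription factor gene Irf1 fell (-0.67 ± 0.07), as did the cytokine gene Tnf (-0.60 ± 0.08) and the adhesion receptor gene Selp (-0.46 ± 0.09). The 1 other tested probe set of Tnf had the opposite sign and did not pass the test. In the list of the amino acid and oxidative stress response, 7 of 26 genes fell and 1 rose, or 10 and 2 adjusted over the list alone, while the list as a whole was not called as shifted (camera adjusted p = 0.066, but 0.011 with quantile normalization and 0.045 without preparation 3). The pseudokinase gene Trib3 fell (-1.02 ± 0.12), as did the serine synthesis enzyme Psat1 (-0.77 ± 0.10), Chac1 (-0.64 ± 0.08) and the asparagine synthetase gene Asns (-0.62 ± 0.10). Cholesterol synthesis and uptake genes were shifted upward, with 3 of 25 higher, or 5 adjusted over the list alone, and none lower (median 0.08, camera adjusted p = 0.036, adjusted p = 0.31 with an estimated correlation). This call also ended without preparation 1 (adjusted p = 0.15), without preparation 2 (0.073) and without control replicate 2 (0.075). Insig1, a regulator of cholesterol synthesis, rose by 0.47 ± 0.07 and Idi1 by 0.42 ± 0.07. Growth factors and matrix signals rose in 2 of 33 cases, or 3 adjusted over the list alone (median 0.09, camera adjusted p = 0.023, adjusted p = 0.30 with an estimated correlation), with the angiogenic factor Vegfa higher by 0.53 ± 0.07. That call ended without preparation 1 (adjusted p = 0.11) and without preparation 3 (0.088). Of the 25 heat shock and protein folding genes 2 rose and 3 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.58), and the co-chaperone gene Bag3 rose by 0.76 ± 0.07.

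As after Ang II, 3 of 19 genes of steroid hormone synthesis rose after potassium, and none fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.13). With the mean of all tested probe sets of a gene in place of 1 probe set, the list was called as higher (adjusted p = 0.045). Star rose 1.27-fold, to 23868 ± 679 (adjusted p = 0.0042), Scarb1 by 0.56 ± 0.07 on the log2 scale and Mrap by 0.44 ± 0.08. Cyp11a1 (-0.06 ± 0.06), Hsd3b1 (-0.02 ± 0.06), Cyp21a1 (-0.02 ± 0.06), Cyp11b1 (0.29 ± 0.11), Agtr1a (0.23 ± 0.10) and Agtr1b (0.16 ± 0.08) did not pass the test. In the list of angiotensin receptors, calcium and kinase signalling, 1 of 31 genes changed, the protein kinase C gene Prkcd, which fell (-0.49 ± 0.08, camera adjusted p of the list 0.17), also adjusted over the list alone.

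**Figure D2:**
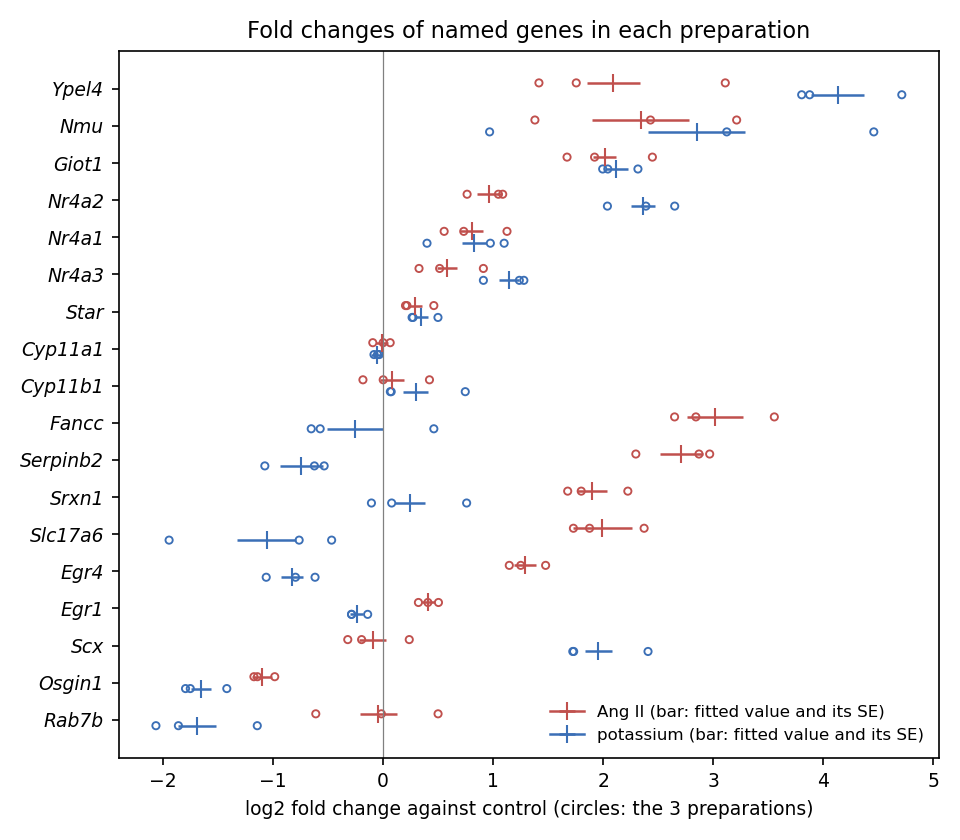
Log2 fold changes against control of 18 named genes, with a circle for each of the 3 preparations and a bar for the fitted value and its SE, Ang II in red and potassium in blue. Where a gene had several probe sets, that with the smallest p against control is drawn, and genes such as Serpinb2 (2.71 after Ang II, -0.75 after potassium) lie on opposite sides of 0.

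Without the replicate block, 506 probe sets passed the test after potassium, without the intensity trend 258 did, and the balance of 518 higher and 480 lower became 612 and 356 with median centring over the tested probe sets and 722 and 177 with scaling to the median of all probe sets, which moved the median log2 fold change of all probe sets from -0.02 to 0.10. The count was 661, 611 and 646 without control replicates 1, 2 and 3, 591 and 579 without potassium replicates 1 and 2, and 432, 565 and 623 without preparations 1, 2 and 3.

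The direct comparison of Ang II with potassium tests which responses differed between the stimuli. Serpinb2 was higher after Ang II than after potassium by 3.46 ± 0.19 on the log2 scale (SE), at 1154 ± 111 against 93.3 ± 31.1 (SD, n = 3). Egr4, a zinc-finger factor of the immediate early list, was 4.34-fold higher, at 2591 ± 702 against 591 ± 189.6. Scx was 4.14-fold lower, at 674 ± 48.9 against 2857 ± 445, and the calcitonin gene Calca was 4.27-fold lower, at 78.0 ± 47.3 against 369 ± 130.1. In total 892 probe sets differed, 576 higher after Ang II and 316 lower, of which 55 and 35 differed by over 2-fold, and 891 of the 892 had the same sign in the 3 preparations.

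The other genes with the largest excess after Ang II were Fancc (log2 difference 3.27 ± 0.25, SE), Slc17a6 (3.05 ± 0.27), the protease gene Prss22 (2.03 ± 0.40), the chromatin protein gene Hmga1 (1.72 ± 0.12), Mapk7 (1.72 ± 0.37) and Srxn1 (1.66 ± 0.13). Those with the largest excess after potassium were Spag4 (-2.45 ± 0.59), Ypel4 (-2.04 ± 0.24), Iqub (-1.87 ± 0.21), Spata2L (-1.72 ± 0.29), the complex I gene Ndufa5 (-1.55 ± 0.16) and Gprc5b (-1.46 ± 0.18). Their adjusted p-values ran from 4.1e-07 for Hmga1 to 0.027 for Spag4, and the call of Spag4 ended in 11 of the alternative settings.

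Of the immediate early transcription factors 12 were higher after Ang II and 7 lower, or 18 and 8 adjusted over the list alone (median log2 difference 0.24, camera adjusted p = 0.0050, adjusted p = 0.23 with an estimated correlation). Beside Egr4, those higher after Ang II included Fosl1 (1.59 ± 0.10) and Egr1 (0.65 ± 0.06), while Junb (-0.65 ± 0.08) was lower. CREB and calcium target genes were shifted the other way, with 9 of 26 lower after Ang II than after potassium and 1 higher, or 15 and 3 adjusted over the list alone (median -0.23, camera adjusted p = 5.8e-06, adjusted p = 0.30 with an estimated correlation). Rgs2 differed by -1.23 ± 0.07, the brighter probe set of Nr4a2 by -1.15 ± 0.14, Bdnf by -0.91 ± 0.13 and Gadd45g by -0.62 ± 0.08. As noted above, the other probe set of Bdnf had the opposite sign. Fosb and the Nr4a genes were members of both lists.

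Genes of the amino acid and oxidative stress response were higher after Ang II than after potassium in 12 of 26 cases and lower in 1, or 14 and 2 adjusted over the list alone (median 0.25, camera adjusted p = 3.8e-06, adjusted p = 0.23 with an estimated correlation). Hmox1, which encodes haem oxygenase 1, differed by 0.57 ± 0.08, Trib3 by 0.87 ± 0.12 and Sesn2 by 0.47 ± 0.08. Cytokines, chemokines and adhesion genes were higher in 3 of 26 cases and lower in none, with 11 higher adjusted over the list alone (median 0.22, camera adjusted p = 2.1e-06, adjusted p = 0.30 with an estimated correlation), among them the chemokine gene Cxcl10 (0.47 ± 0.07). Heat shock and protein folding genes were higher in 6 of 25 cases and lower in 1, or 9 and 1 adjusted over the list alone (median 0.07, camera adjusted p = 0.0055, adjusted p = 0.31 with an estimated correlation), with Cryab higher by 0.47 ± 0.07 and Bag3 lower (-0.48 ± 0.07). Feedback regulators were higher in 6 of 32 cases and lower in 1, or 8 and 2 adjusted over the list alone, without a shift of the list (camera adjusted p = 0.51). Spry2 (0.78 ± 0.07), Errfi1 (0.79 ± 0.08) and the phosphatase gene Dusp5 (0.79 ± 0.08) were higher after Ang II.

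Steroid hormone synthesis genes differed in 1 of 19 cases, the electron donor gene Por, which was higher after Ang II (0.37 ± 0.08, adjusted p = 0.0098), while 1 was higher and 2 lower adjusted over the list alone (camera adjusted p = 0.26). The call of Por ended in 7 of the alternative settings. Star did not differ past the threshold between the stimuli (-0.05 ± 0.06, adjusted p = 0.78). Cholesterol synthesis and uptake genes were higher after Ang II in 2 cases, among them Msmo1 (0.72 ± 0.08), and lower in 1 of 25 (3 and 2 adjusted over the list alone, camera adjusted p = 0.69). Growth factors and matrix signals were higher in 6 and lower in 2 of 33 cases (6 and 5 adjusted over the list alone, camera adjusted p = 0.85), with Mmp3 higher by 1.18 ± 0.15 and Wnt4 lower (-0.41 ± 0.07). Of the angiotensin receptor, calcium and kinase signalling list, Prkcd was higher after Ang II (0.66 ± 0.08), and it was the only call among 31 genes, over all probe sets and adjusted over the list alone (camera adjusted p = 0.089).

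Without the replicate block 442 probe sets differed between the stimuli, without the intensity trend 156, and with scaling to the median of all probe sets 557. The count was 430, 486 and 576 without Ang II replicates 1, 2 and 3, 516 and 549 without potassium replicates 1 and 2, and 275, 537 and 553 without preparations 1, 2 and 3.

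**Figure D3:**
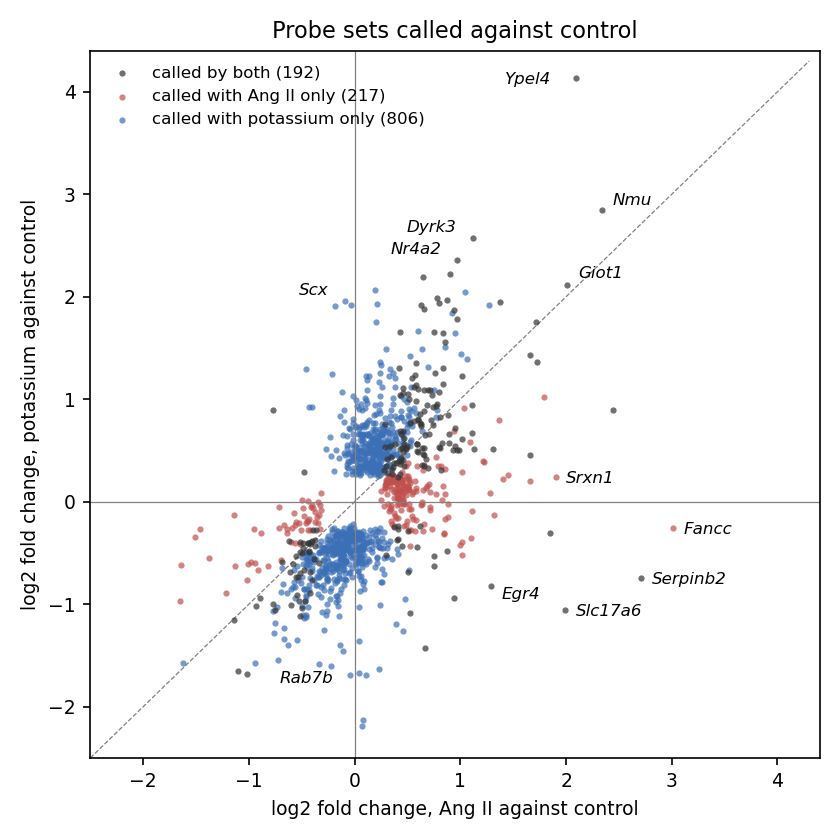
Log2 fold change after potassium (vertical) against that after Ang II (horizontal) for the 1215 probe sets called against control by either stimulus, with the line of equal change dashed. Of these, 192 were called by both, 217 with Ang II only and 806 with potassium only, and Serpinb2, Slc17a6 and Egr4 lie in the quadrant of opposite calls.

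The comparison of both sets of calls asks how far the responses to the stimuli were shared. Ang II and potassium changed 169 probe sets in the same direction, 126 higher and 43 lower. Lists of the same length drawn independently would share 8.62 higher and 2.55 lower. Giot1 and Nr4a1 were raised by both, with direct differences of -0.10 ± 0.10 and -0.02 ± 0.11 on the log2 scale, neither past the threshold. Of the 169 shared probe sets 58 also differed directly between the stimuli, 44 of them larger in potassium, such as Ypel4 and the brighter probe set of Nr4a2, and 14 larger in Ang II. A further 23 probe sets were called in opposite directions, 21 of them higher after Ang II and lower after potassium against 7.99 for independent lists, and the direct difference of all 23 was past the threshold, which opposite calls with 1 common error entail. Among the 217 probe sets called with Ang II alone 115 differed directly from potassium, and among the 806 called with potassium alone 368 differed directly from Ang II.

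Both comparisons used the same control arrays, which gives the fold changes a correlation with no effect at all. Across the tested probe sets, which are not independent replicates, the correlation of the fold changes was 0.55. Arrays simulated without any effect, the shared controls included, gave 0.50 with independent genes, and 0.44 when whole-array deviations were resampled (from -0.90 to 0.98 over 100 draws). The covariance was 0.045, against 0.018 with independent genes and 0.020 with whole arrays, where the draws ran from -0.023 to 0.10 and so include the observed value. With no effect almost nothing is called in either comparison, so the simulated overlap of calls was bound to be near 0. It was 0.04 probe sets on average and at most 1 with independent genes, and 0 with whole arrays. It therefore cannot show how far the shared controls add to the observed overlap. With 3 controls the group could not be split into parts of 2 or more each, so part of the overlap may come from the shared controls. In a comparison chosen after the data were seen, the Ang II fold change of 1 preparation was set against the potassium fold change of another, which share no array. The covariance was 0.017 on average over the 6 pairs (0.011 to 0.028) and the correlation 0.10 (0.065 to 0.15), and labelling that differed in both stimulated groups could add to it. Without the replicate block 84 probe sets were changed by both, and without the intensity trend 16. The 126 higher and 43 lower became 156 and 27 with median centring, and 184 and 8 with scaling to the median of all probe sets. The overlap was 124, 100 and 122 without control replicates 1, 2 and 3, 103, 103 and 107 without Ang II replicates 1, 2 and 3, and 68, 97 and 104 without preparations 1, 2 and 3.

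**Figure D4:**
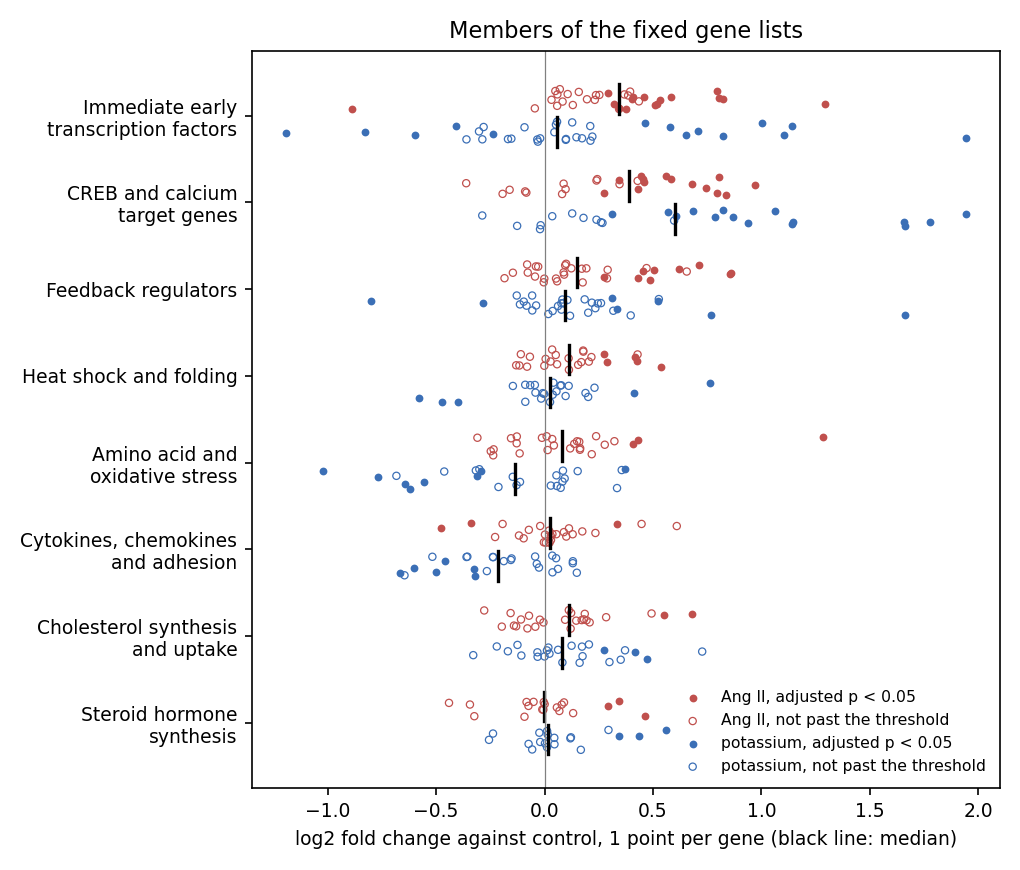
Log2 fold change against control of each measured member of 8 fixed gene lists, Ang II in red and potassium in blue, filled where the adjusted p was under 0.05, with the median as a black line. The CREB and calcium target genes have medians of 0.39 after Ang II and 0.60 after potassium.

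Markers of 10 adrenal and blood cell types were tested as lists in the same 3 comparisons, and none of the lists was called as shifted. The smallest camera adjusted p over the comparisons was 0.066 for zona glomerulosa, 0.12 for zona fasciculata, 0.20 for medulla (chromaffin cells), 0.47 for endothelium, 0.35 for macrophage, 0.29 for capsule fibroblast, 0.64 for smooth muscle and pericyte, 0.75 for T and B lymphocyte, 0.93 for red blood cell and 0.71 for adipocyte markers. The zona glomerulosa markers, with a median log2 fold change of 0.11 after potassium, were called as higher with the mean of all tested probe sets of a gene (adjusted p = 0.043), without control replicate 2 (0.020) and without preparation 2 (0.025). Single markers that passed the test against control were Wnt4, a zona glomerulosa marker, lower after Ang II (-0.32 ± 0.07), Mrap, in the zona fasciculata list, higher after both stimuli, and Acta2, a smooth muscle marker, higher after Ang II (0.40 ± 0.10). The lists of red blood cell, adipocyte and zona fasciculata markers had 3 tested members each. The 3 tested zona fasciculata markers had high signals on every array, Akr1b7 (27524 to 29964), Mrap (2979 to 6474) and Cyp11b1 (1839 to 5413). So did some markers of other cells, such as Hbb (15618 to 20314), Mgp (11736 to 15976), Kdr (6875 to 8654) and Cd74 (6117 to 9383). Others were low, such as Fcgr1a (154 to 251). From these values a change cannot be assigned to 1 cell type.

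The log2 ratio of the 3′ to the 5′ signal of Gapdh lay between 0.39 and 0.67 on the 9 arrays, and that of beta-actin between 1.41 and 1.85. For Gapdh it was lower than in the control of the same preparation in all 3 preparations, with differences of -0.04, -0.02 and -0.22 after Ang II and -0.18, -0.21 and -0.09 after potassium. For beta-actin the differences were -0.17, -0.05 and -0.26 after Ang II, and -0.08, -0.23 and 0.06 after potassium. Control replicate 2 stood apart from the other arrays. The median deviation of its dim probe sets from the mean of all 9 arrays, itself included, was 0.23 on the log2 scale. For its bright probe sets it was -0.09, and its weight in a weighted fit was 0.43 against 0.91 to 1.68 for the others. The decreases after Ang II numbered 46, 45 and 51 without control replicates 1, 2 and 3, and those after potassium 255, 281 and 284, against 99 and 480 with all arrays.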

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

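The tests on control replicate 2 and on the amount of poly-A control RNA were chosen only after the results were seen, while the splits of the arrays and the test of other probe sets of the same genes were set down before their results.

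Ang II and potassium moved 23 probe sets in opposite directions against control, and these drew attention because the effects of the stimuli differed. Of these, 21 rest on a decrease after potassium. Scaling to the median of all probe sets cut such decreases from 480 to 177, and how many of the 21 remained was not counted. The limma adjusted p after potassium was 0.037 for Serpinb2, 0.031 for Slc17a6 and 0.033 for Pex11a, but 4.2e-05 for Sdc1 and 9.6e-05 for Egr4. The direct difference is the sum of the sizes of the opposite effects with the same standard error, so it passes the threshold by construction and adds no further evidence. For the named genes with the smallest p, chosen after their values were seen, Ang II exceeded potassium on the log2 scale by 2.12 for Egr4, 3.46 for Serpinb2, 1.61 for Sdc1, 1.03 for Prkaa1, 0.78 for Plin2, 0.81 for Anxa2, 3.05 for Slc17a6 and 1.35 for Pex11a. Their adjusted p-values in limma's direct contrast ran from 9.8e-09 for Egr4 to 8.2e-06 for Pex11a. Sdc1, which encodes the heparan sulphate proteoglycan syndecan 1, rose by 0.52 after Ang II and fell by 1.09 after potassium. Plin2, which encodes a coat protein of lipid droplets, rose by 0.40 and fell by 0.38, and Prkaa1, a catalytic subunit of AMP-activated protein kinase, rose by 0.59 and fell by 0.44. A deviation of the shared control arrays would move both fold changes the same way. The estimate of the direct difference does not use those arrays, although its standard error does, through the pooled spread.

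For each of the 3 comparisons, the 6 arrays were divided in all 10 ways into groups of 3, with the preparation kept as a block. For Ang II against control the real division called 409 probe sets and the highest other 0, so 1 of 10 divisions was as large. The values were 998 and 0 for potassium against control (1 of 10) and 892 and 0 for Ang II against potassium (1 of 10). The highest other division held 1390, 1640 and 987 probe sets at an unadjusted p of 0.05, against 2694, 3496 and 3017 for the real ones. The 4 divisions of each comparison that part all 3 preparations gave 0 as well, apart from the real one. With 10 divisions a share under 0.05 cannot be reached. In the other divisions any real effect also enters the residual spread and lowers their counts, so 0 is not the level of random division alone.

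Control replicate 2 had raised dim probe sets, and that array may have made probe sets look lower in the stimulated groups. If it made most of the decreases, leaving it out would remove more of them than leaving out another control. For Ang II, 45 decreases were called without it, against 46 and 51 without control replicates 1 and 3, a ratio of 0.978 to the lower count. For potassium the counts were 281, 255 and 284, a ratio of 1.10, so leaving out this array removed about as many decreases as leaving out another control. Each such fit also had a control fewer, and leaving out an outlying array can narrow the pooled spread and add calls. The counts therefore cannot decide whether this array made most of the decreases. A real fall of transcripts after the stimuli remains open, and scaling to the median of all probe sets left 33 decreases after Ang II and 177 after potassium.

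Control probe sets, which no comparison used, held a signal on the potassium arrays. The 5′ probe set for the spiked bacterial dap transcript was higher than on the control arrays by 0.56 on the log2 scale (adjusted p = 0.11) and the middle probe set for thr by 0.47 (limma, adjusted p = 0.11). They were the 2 of 57 control probe sets that were higher after potassium at p under 0.01, where 0.285 would be by chance; 1 was lower, and none passed the adjusted threshold. More poly-A control RNA per sample RNA would raise both ends of a transcript alike. The 5′ rise exceeded the 3′ rise by 0.46 ± 0.15 (SE, n = 3 preparations) for dap, whose 5′ end was picked for its rise, and by 0.23 ± 0.24 for thr (0.43, -0.25 and 0.51 in the preparations). In the same series of probe sets, lys differed from control by -0.18 ± 0.19 (3′), 0.15 ± 0.16 (5′) and 0.07 ± 0.11 (middle). For phe the differences were 0.07 ± 0.12, 0.23 ± 0.12 and 0.57 ± 0.17. More poly-A control RNA therefore stays open as an explanation. Labelling that reached further 5′ could shift single probe sets by position, but the log2 ratio of the 3′ to the 5′ signal does not settle it, with differences from control of -0.18, -0.21 and -0.09 for Gapdh, which was lower in the 3 Ang II arrays too, and of -0.08, -0.23 and 0.06 for beta-actin. Of 184 other probe sets of genes that fell, 75.5% shared the sign of the call (exact 95% interval 68.7 to 81.6). For genes that rose, 84.1% of 296 did (79.5 to 88.1). These intervals treat probe sets as independent, although some belong to the same gene and all share the same arrays. They therefore do not cover the spread between preparations. The share to expect from labelling alone is not known either, since probe sets of a gene share RNA and array deviations. Most other probe sets thus went with the call, but this cannot decide whether such labelling made the potassium calls. Its part in single probe sets and a difference in the RNA or its labelling stay open too.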

How the results depend on the processing

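Scaling to the median of all probe sets, the fold changes set against each other between preparations, and the list tests without control replicate 2 were chosen after seeing the data. Without the replicate block, which ignores the pairing by preparation, 197 probe sets were called after Ang II, 506 after potassium, 442 between the stimuli and 84 by both, against 409, 998, 892 and 169. It ended 43 of the 168 calls of named genes and 1 list call (cytokines after potassium), and added 1 list call (immediate early transcription factors after potassium). Without the intensity trend the counts were 38, 258, 156 and 16, and 98 named calls ended. Scaling to the median of all probe sets gave 557 between the stimuli and ended 21 named calls. The cause was not tested in these cases. Under the other settings that kept every array the 4 counts stayed within 1.5 times, at 325 to 475, 816 to 1082, 736 to 1147 and 137 to 193, and with the arrays of the groups compared alone the first 3 were 361, 768 and 962. Leaving out arrays or preparations gave 143 to 454, 432 to 977, 275 to 1012 and 68 to 140, with fewer arrays in each fit. After Ang II the count was 211, 221 and 233 without Ang II replicates 1, 2 and 3, 277, 244 and 274 without control replicates 1, 2 and 3, and 143, 254 and 244 without preparations 1, 2 and 3. After potassium it was 661, 611 and 646 without control replicates 1, 2 and 3, 591 and 579 without potassium replicates 1 and 2, and 432, 565 and 623 without the preparations. Between the stimuli it was 430, 486 and 576 without Ang II replicates 1, 2 and 3, 516 and 549 without potassium replicates 1 and 2, and 275, 537 and 553 without the preparations. By both it was 124, 100 and 122 without control replicates 1, 2 and 3, 103, 103 and 107 without Ang II replicates 1, 2 and 3, and 68, 97 and 104 without the preparations. Where an arm kept 2 arrays its spread was pooled with the other groups. No named call and no list direction past the threshold reversed under any setting run. Of the 168 named calls 69 were kept under all settings apart from those leaving out a preparation. The most often lost were Plat and Sdf2l1 after potassium (19 settings each), Cyp51 after potassium (18), and Dnajb1 and Rpusd3 after Ang II and Insig1 between the stimuli (16 each). Camera with an estimated correlation ended 14 of the 15 list calls. Among these were growth factors after potassium and immediate early transcription factors between the stimuli. Their estimated correlations were -0.028 and -0.003, below the preset 0.01, so a higher correlation between genes does not account for those losses. With an estimated correlation camera tests on the 4 residual degrees of freedom, which by itself raises p. A call lost in this version therefore does not by itself show that members are correlated. Fry tests a list against no change and not against the other genes, so it answers another question and neither ends nor adds a call. Of the lists called by camera it did not pass cholesterol synthesis after potassium (adjusted p = 0.082) and oxidative phosphorylation between the stimuli (0.22). Of those not called it passed growth factors after Ang II (0.0056) and immediate early transcription factors (0.018) and the amino acid and oxidative stress response (0.020) after potassium. Camera on the mean of all tested probe sets of a gene ended none and added 4, growth factors after Ang II (0.043) and, after potassium, steroid hormone synthesis (0.045), immediate early transcription factors (0.037) and zona glomerulosa markers (0.043). Signals near the upper or lower end of the arrays' range limit what fold changes can show.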

Other observations

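The comparison of ERK target genes was chosen only after the list results were seen, while the gene lists and the rule for their named members were fixed earlier. Circadian clock genes moved in both directions after potassium. Of 17 measured, 5 rose and 2 fell, or 5 and 5 adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.95, median log2 fold change -0.12 with an upward camera direction). The nuclear receptor gene Rora rose by 0.90 ± 0.12 (SE, n = 3 per group), the clock repressor gene Cry2 by 0.70 ± 0.12 and Bhlhe40 by 0.67 ± 0.12, while its relative Bhlhe41 fell (-0.53 ± 0.13). After Ang II, 1 rose and 1 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.70). In the direct comparison 1 was higher after Ang II and 4 were lower, or 3 and 7 adjusted over the list alone (camera adjusted p = 0.20), with Cry2 lower after Ang II than after potassium (-0.66 ± 0.12).

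Among 43 genes of oxidative phosphorylation, potassium raised 2 and lowered none, also adjusted over the list alone (camera adjusted p = 0.47). Both encode subunits of complex I of the respiratory chain, Ndufa5 (1.75 ± 0.16) and Ndufs4 (0.47 ± 0.11). The call of Ndufs4 ended in 10 of the alternative settings and that of Ndufa5 in 0. After Ang II none passed limma's test, also adjusted over the list alone, and 9 were lower at an unadjusted p of 0.05 (camera adjusted p = 0.17). The list was called as lower after Ang II with quantile normalization (adjusted p = 5.3e-05), without control replicate 2 (0.0099) and without preparation 2 (0.016). In the direct comparison 2 genes were lower after Ang II, or 3 adjusted over the list alone, and the list was shifted downward (median -0.07, camera adjusted p = 0.0090, adjusted p = 0.70 with an estimated correlation), a call that ended without preparation 3 (adjusted p = 0.091). In the list of potassium, calcium and sodium transport, the calcium pump gene Atp2b1 rose after Ang II (0.42 ± 0.08), the only call among 24 genes (camera adjusted p = 0.59). The potassium channel gene Kcnk5 rose after potassium (0.72 ± 0.17, camera adjusted p of the list 0.71) and was lower after Ang II than after potassium (-0.77 ± 0.17, camera adjusted p of the list 0.69). Of 25 cell cycle genes, the inhibitor gene Cdkn1a rose after Ang II (0.41 ± 0.08, camera adjusted p of the list 0.68). None was called after potassium in limma's test, where 3 were higher at an unadjusted p of 0.05 (camera adjusted p = 0.68). Between the stimuli Cdkn1a was higher after Ang II (0.38 ± 0.08) and Cdkn1b lower (-0.31 ± 0.08, camera adjusted p of the list 0.99). The transport and cell cycle counts were the same adjusted over the list alone. The calls of Cdkn1b and Cdkn1a between the stimuli ended in 14 and 9 of the alternative settings, and the 1 other tested probe set of each gene had the opposite sign there without passing the test. The call of Cdkn1a after Ang II ended in 9, that of Kcnk5 after potassium in 7 and that of Atp2b1 in 6, and 1 of the 2 other tested probe sets of Atp2b1 had the opposite sign.

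The opposite calls of Egr1, Egr4 and Dusp5 led to the hypothesis that transcription driven by ERK, a MAP kinase, may be higher after Ang II than after potassium. It was tested on a list of 15 ERK target genes written without Egr1, Egr4 and Dusp5. Of its members 10 also lay in the lists already computed. Among the 13 tested, 2 were higher after Ang II than after potassium, Plaur (0.48 ± 0.09, SE) and Epha2 (0.36 ± 0.08), and none was lower. The median log2 difference was 0.078 and camera gave p = 0.34 (p = 0.52 with an estimated correlation), so the list neither bears out the hypothesis nor excludes it.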
